A study of Mus musculus with 5 samples.

How the data were processed

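RNA and DNA were extracted from HL-1 cells and from the microvesicles these cells release, and all 5 extracts were hybridised as labelled cRNA to Illumina mouse BeadChips with 25697 probes and 1 colour. HL-1 is a mouse atrial cardiomyocyte line. There were 2 microvesicle RNA arrays, 2 cell RNA arrays and 1 microvesicle DNA array, with groups and replicate numbers taken from the sample titles. The microvesicle DNA was given a poly-T tail with terminal transferase so that it could be copied and labelled like RNA, per the labels' protocols. Chip 1 held both cell arrays and microvesicle RNA array 1, and chip 2 held microvesicle RNA array 2 and the DNA array. The labels do not say that replicates came from separate cultures, so limma's p-values for probes measure the spread between these samples, which may be technical.

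The authors deposited a table that was not normalized and a table of processed values. The first gives, per the file headers, the mean bead intensity of each probe on a linear scale without background subtraction, with the standard error of the bead intensities. Its detection p-value, as deposited, moves in steps that fit 798 negative control probes and gives the share of such controls at or above a probe's intensity. The deposited number of beads behind each mean is a whole number. BeadStudio 3.3 is named in the submitters' processing notes. The processed values that the authors deposited are background-subtracted intensity values on a linear scale, judged from values below 0 and nearly equal medians (3.50 to 3.51 on the 5 arrays). In rank they match the raw signal of the same array (rank correlation 1). The method of that normalization is not given in the sources used here. That table stretched the DNA array furthest, to a highest value of 2239456 against 15568 to 44614 on the RNA arrays, so it served only as an alternative.

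Raw signals were background-corrected and normalized with limma 3.58.1 in R 4.3.3. The function neqc was used on the 4 RNA arrays, with the negative control level inferred from the detection p-values, an offset of 16 and quantile normalization, which gives every array the same distribution. The offset compresses differences of dim probes. A probe counted as detected on an array at a detection p under 0.01, which chance alone gives to 257 probes per array. Probes detected on at least 2 of the 4 RNA arrays were tested with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No block was used for chip or replicate number. Intervals of shares are exact binomial 95% intervals over probes, which are not independent of each other.

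Where a probe was not detected on either array of a group, only a bound was given. The bound sets the brighter group's mean log2 value against the dimmer group's mean of the higher of the probe's own value and the lowest value among detected probes of each array. The fold was written as at least that size.

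Gene names came from the platform annotation supplied with the processed values. It gives 1 symbol for 23978 probes, 16593 genes in all, and none for 1719 probes. Of the named probes, 23962 were found by gene identifier in the RefSeq table of GRCm38.p6, and 0 symbols changed. The brightest probe over the 4 RNA arrays stood for each gene. Among 439 genes with several tested probes, 118 had probes whose differences took opposite signs. Such disagreement is given where it concerns a named gene.

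There were 31 gene lists, fixed before the data were examined. Members that matched no symbol on the array were looked up through RefSeq synonyms. They cover the sarcomere, calcium handling and ion channels, cardiac transcription factors, secreted factors, cytosolic and mitochondrial ribosomal proteins, translation factors, the respiratory chain, the proteasome, glycolysis, fatty acid oxidation, cholesterol synthesis, the cell cycle and histones. Others cover vesicle release, chaperones, the unfolded protein response, immediate early genes, nuclear noncoding RNAs, zinc finger proteins, RNA processing and the cytoskeleton. A further 8 lists hold markers of other cell types, and olfactory and vomeronasal receptor genes served as a list that heart cells are not known to use. The 21 lists with 5 or more tested genes were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other tested genes, while fry, run as an alternative, tests whether the genes of a list move one way on balance. At a preset correlation camera takes its degrees of freedom from the number of genes, so genes and not arrays act as its replicates. Such p-values do not measure the spread between arrays. With an estimated correlation, run as an alternative, camera takes its degrees of freedom from the arrays.

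The rule for the genes named in the RNA comparison was also fixed before the data were examined. It takes genes past the threshold or, since none passed, the 10 with the smallest unadjusted p as values only. It adds the 10 genes with the highest microvesicle value, from each list the 2 members with the highest cell value where none passes, and 10 fixed heart and reference genes. Members picked for a high cell value may lie lower in microvesicles than the rest of their list, so they do not stand for it. Lists with fewer than 5 tested genes are given as counts. For the DNA array it takes the 10 detected genes with the highest signal and the 10 with the largest difference from the highest RNA array. Unnamed and predicted genes were counted but skipped in naming.

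With 1 DNA array there was no replicate check, and no test was run on it. Raw signals with the standard error over beads are given. Correlations with the RNA arrays used neqc over all 5 arrays. The list medians, set among 10000 random lists matched on mean value, are left out because most list genes lay at background on the DNA array. Quantile normalization gives the DNA array the same distribution as the RNA arrays although few of its probes stood above background, so log2 differences of single probes are not given for it.

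The procedure was tested on simulated data with 200 of the 3878 probes changed in each of 5 runs. With the spread of the 2 cell arrays, 85.2% of probes changed 2-fold and 98.8% of those changed 4-fold were recovered, with a mean of 8.8 false calls per run. With the spread of all 4 RNA arrays, 0% were recovered even at 16-fold, although 98.8% of those had the right sign. In the list test, a list of 40 genes shifted by 2 on the log2 scale was found in 50 of 50 runs and an unshifted list in 1 of 50. The simulated genes were drawn independently, so these runs cannot show how correlation between the genes of a list affects camera. In the data the estimated correlation of the ribosomal list was 0.045.

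Alternatives covered background correction, normalization between arrays, the deposited processed values, the filter on dim probes, chip and replicate number as blocks, the variance model, the threshold, the detection p, the list test, the probe per gene and leaving out each array in turn. A crossed pairing of replicate numbers and list tests with chip or replicate blocks were added after seeing the data. The block check found that same-numbered arrays deviated from their group means with a correlation of -0.24 over 3878 probes.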

Results

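The series asked which transcripts and DNA sequences are carried by microvesicles from cultured heart muscle cells, and how the vesicle RNA compares with the RNA of the cells that release them. The cells were HL-1, a mouse atrial cardiomyocyte line that keeps a heart muscle phenotype while dividing in culture. Signals were raw bead intensities, with a median of 41 beads behind each probe. The median raw signal was 63.0 and 90.9 on microvesicle RNA arrays 1 and 2, 63.6 and 62.6 on cell RNA arrays 1 and 2, and 70.2 on the microvesicle DNA array. Detected probes numbered 2024 and 5605 on the microvesicle RNA arrays, 4179 and 3629 on the cell RNA arrays and 343 on the DNA array, where chance gives 257 on each. The number of arrays, 2 per RNA group and 1 for DNA, limits the precision of every comparison.

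**Figure D1:**
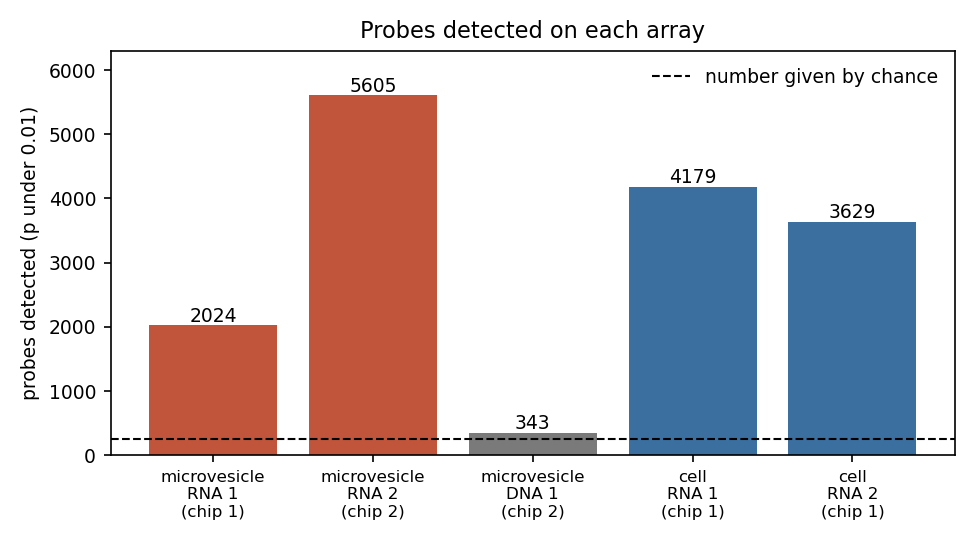
Number of probes detected at p under 0.01 (vertical axis) on each of the 5 arrays (bars), with the number that chance gives as a dashed line at 257. Microvesicle RNA array 2 had the most detected probes (5605), and the DNA array (343) lay close to chance.

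The first comparison was which transcripts were present in vesicles and cells. Nearly everything that both microvesicle arrays detected was also detected in the cells. Both microvesicle arrays detected 1595 probes of 1359 genes, and both cell arrays detected 3470 probes of 2826 genes. Of the 1595 vesicle probes, 1531 (96.0%, 94.9 to 96.9) were on both cell arrays, where independent lists of these sizes would share 215. In the other direction, 44.1% (42.5 to 45.8) of the cell probes were on both microvesicle arrays, and 1051 of the 3470 were on neither.

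A small set of 26 probes was detected on both microvesicle arrays and neither cell array. The brightest named ones, picked out after their values were seen, were Wbp1l (at least 18.2-fold higher in the microvesicle mean) and the small GTPase gene Rab28 (at least 16.9-fold). They were followed by the Arp2/3 complex subunit gene Arpc1a (at least 9.95-fold), the pyrophosphate transporter gene Ank (at least 8.70-fold) and the transcription factor gene Zeb1 (at least 6.89-fold). These bounds are for the mean of the microvesicle arrays, not for each array, and rest mainly on microvesicle array 2. Without it, the log2 differences of these genes lay between 1.85 and 2.19. Their log2 values on microvesicle array 1 were 6.78 to 7.24, close to the lowest detected value of 6.51 on that array. At the detection threshold used, chance alone passes a share of 0.01 of absent probes on an array. Microvesicle array 2 alone among the RNA arrays detected 3166 probes, and that share of so many is no smaller than the 26. Chance on microvesicle array 1 could therefore give a set of this size. Single probes were not tested for it, so the presence of the 26 probes on microvesicle array 1 stays uncertain. The raw signal of Wbp1l was 91.8 on array 1 and 4362 on array 2, and that of Rab28 was 91.7 and 3778. With limma their adjusted p-values were 0.206 and 0.201.

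The microvesicle arrays differed from each other. Of the probes on microvesicle array 1, 92.7% (91.5 to 93.8) were on both cell arrays, against 37.0% (35.7 to 38.3) of those on microvesicle array 2. Microvesicle array 2 alone among the RNA arrays detected 3166 probes of 2672 genes, and microvesicle array 1 alone detected 41 probes. The brightest of those 3166, again picked out after their values were seen, were Get1, a factor for inserting tail-anchored proteins into the endoplasmic reticulum (raw signal 8982), the zinc finger gene Zmat3 (7559) and the ubiquitin ligase gene Rnf11 (7436). On microvesicle array 1 the raw signals of these 3 lay between 63.4 and 77.1. Over the tested probes, the normalized log2 values of the cell arrays correlated at 0.99 across probes and those of the microvesicle arrays at 0.58. Microvesicle array 1 correlated with both cell arrays at 0.79, and microvesicle array 2 at 0.33 and 0.29. Probes are not independent replicates, so these values describe the arrays only.

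**Figure D2:**
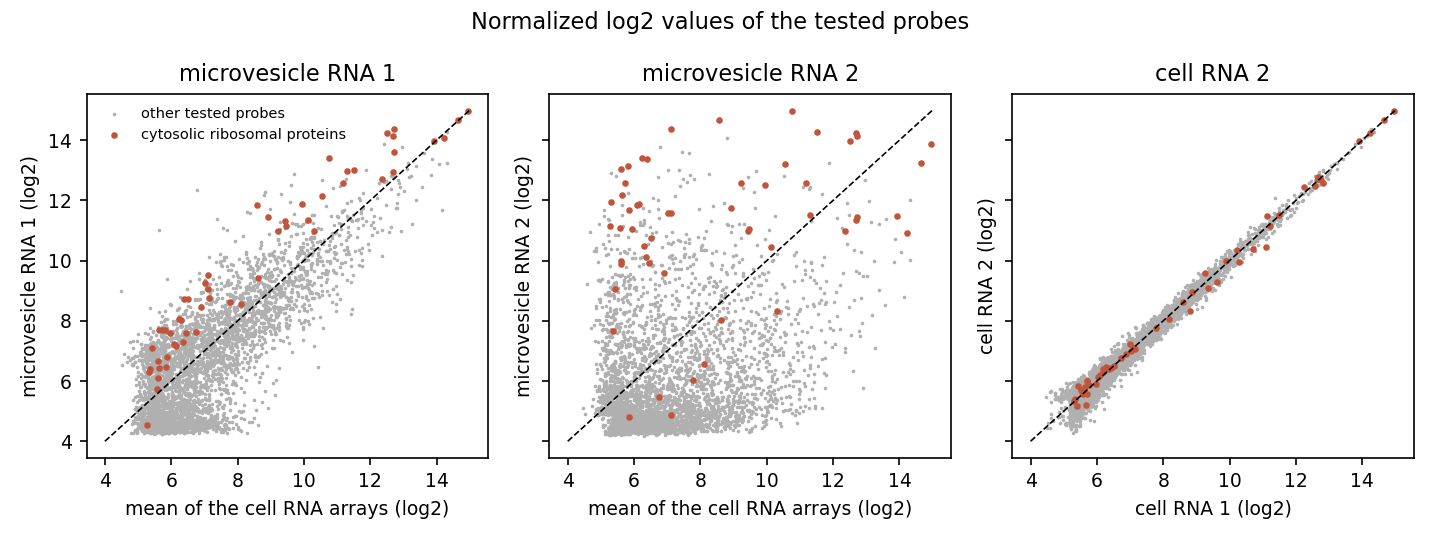
Normalized log2 values of the tested probes, with each microvesicle RNA array against the mean of the cell RNA arrays in the left and middle panels and cell array 2 against cell array 1 on the right. Points are probes, cytosolic ribosomal protein probes are coloured and the dashed line marks equal values. The cell arrays correlate at 0.99, while microvesicle array 2 is widely scattered against the cells.

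The second comparison was the level of each transcript in microvesicles and cells. Ribosomal protein transcripts stood higher in microvesicles than other tested genes by camera, with genes as its replicates (adjusted p = 1.52e-15). This call was lost with an estimated correlation (adjusted p = 0.600), where the degrees of freedom come from the arrays. The genes with the smallest p-values were mostly lower or not detected in microvesicles. Among the highest microvesicle values were Rpl37 (log2 difference 4.67 ± 1.12, SE, n = 2 per group) and Rpl23 (3.42 ± 0.70), and outside the ribosome Wsb2, a SOCS box ubiquitin ligase adaptor (6.29 ± 0.62). No single probe passed the test. In limma, 0 of 3878 probes (3123 genes) were higher and 0 were lower at an adjusted p of 0.05. The smallest adjusted p was 0.0917, shared by 215 probes. At an unadjusted p under 0.05, 214 probes were higher and 900 lower in microvesicles, where chance gives 194 in all. This balance depends on the filter, as the 1531 probes detected on all 4 RNA arrays gave 108 higher and 52 lower.

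This count of 0 depended on the spread, the scaling and the filter used. With chip as a block, limma called 968 probes higher and 1735 lower, and within chip 1, without microvesicle array 2, it called 997 and 1701. Without microvesicle array 1 it called 665 higher and 2718 lower. These 3 fits draw their spread from the cell arrays alone, so the microvesicle arrays are assumed to vary as little as the cells. Median scaling in place of quantile normalization gave 7 higher and 1651 lower, no normalization gave 5 and 1416, a variance trend gave 10 and 677, and no filter gave 16 and 163.

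The median log2 difference of the tested probes was -0.87, with -0.37 on microvesicle array 1 and -1.30 on microvesicle array 2. Among them, 3470 were detected on both cell arrays and 1595 on both microvesicle arrays, so most entered through the cells. The median was -0.35 with a filter at detection p 0.05 and 0.016 over all 25697 probes, where quantile normalization gives the arrays the same distribution. In 2000 probes both microvesicle arrays lay below both cell arrays and in 557 above, together 65.9%. Chance would give 33.3% only if the 4 arrays were interchangeable. They were not, as the median absolute log2 difference was 0.16 between the cell arrays and 1.29 between the microvesicle arrays. The 33.3% is therefore no fair reference for this share. The filter favours probes that lie below, since most were admitted by the cell arrays, and among the 1531 probes on all 4 arrays 545 lay below and 396 above. A difference of at least 2-fold in both microvesicle arrays was seen in 1012 lower and 257 higher probes.

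Of the 10 genes with the smallest p-values, all at an adjusted p of 0.0917 in limma, 9 were lower in microvesicles and not detected on either microvesicle array. They included the lysosomal carboxypeptidase gene Ctsa (at least 7.64-fold lower), the RNA helicase gene Ddx5 (at least 9.24-fold), the membrane metalloproteinase gene Mmp14 (at least 7.19-fold) and the nuclear pore gene Aaas (at least 6.90-fold). The others were Maea, a subunit of a ubiquitin ligase complex (at least 6.63-fold), the lipid carrier gene Apoe (at least 5.95-fold), Ppfibp2 (at least 5.21-fold), Afmid of tryptophan breakdown (at least 5.00-fold) and the mitochondrial gene Mettl17 (at least 4.51-fold). Another probe each of Ppfibp2, Afmid and Mettl17 gave smaller differences of -1.84, -1.01 and -1.68. The exception was the protein kinase gene Prkx, with log2 values of 9.40 on both microvesicle arrays and 5.81 and 5.93 on the cell arrays. Values at background differ little between arrays, which favours undetected genes in a ranking by p. The microvesicle log2 values of Ctsa had an SD of 0.16. Those of Kcnh2, detected on both microvesicle arrays with a difference of -3.98, had an SD of 2.86. The rank of the 9 genes therefore does not mark them as the most depleted.

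Among the 10 genes with the highest microvesicle values, 8 encode ribosomal proteins. Rpl41 was higher in microvesicles by 2.13 ± 0.57 on the log2 scale, Rpl9 by 1.58 ± 0.34, Rps19 by 1.54 ± 0.33 and Rpl38 by 1.5 ± 0.32, with adjusted p-values from 0.103 to 0.127 in limma. With median scaling Rpl41, Rpl9, Rps19 and Rpl38 were higher by 1.35, 0.91, 0.78 and 0.75. In the main fit a second probe of Rps19 gave -0.31 and a second probe of Rpl38 -0.45. Rplp1 (-0.53 ± 0.51) and Rps2 (-0.70 ± 0.61), the brightest probes of the cells, differed by about their error. Quantile normalization gave each of them the same value on microvesicle array 1 and both cell arrays, so these differences rest on microvesicle array 2. With no normalization they were -0.88 and -1.18. Trak2, an adaptor for mitochondrial transport, was higher by 3.24 ± 0.32, with log2 values of 12.89 and 12.97 on the microvesicle arrays and an adjusted p of 0.0917. Wsb2 had the same adjusted p. A second Trak2 probe was detected on microvesicle array 2 alone.

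Of the 48 tested cytosolic ribosomal protein genes, 35 lay above both cell arrays on both microvesicle arrays and 1 lay below. The list's median log2 difference was 2.20, with 1.42 on microvesicle array 1 and 2.73 on microvesicle array 2, against -0.84 over all tested genes. No member passed the threshold over all probes and 0 passed adjusted over the list alone, while 18 were higher at an unadjusted p under 0.05. Camera placed the list above the other genes (adjusted p = 1.52e-15), with genes and not arrays as its replicates. This call was lost with an estimated correlation (camera unadjusted p = 0.0286, adjusted p = 0.600). That setting put a correlation of 0.045 in place of 0.01 and also took its degrees of freedom from the arrays. The loss is therefore not due to correlation between genes alone. Fry, which asks for a shared direction without a comparison with other genes, gave an adjusted p of 0.0868. The call of camera was made again with chip as a block, at a median of 1.42, and on leaving out any array.

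Many differences of single genes rest on microvesicle array 2. Of the 69 tested genes named, 35 fell under 0.5 times their difference or changed sign without it. Heart muscle genes had no list past the threshold. Of 18 tested sarcomere genes, 10 lay below the cells on both microvesicle arrays and 3 above, with a median of -0.91 (camera adjusted p = 0.808). The atrial light chain gene Myl4, with normalized log2 values of 12.09 and 12.22 in microvesicles, was close to its level in the cells (0.50 ± 0.34), and it turned to -0.53 with median scaling. Tnnc1, the slow and cardiac troponin C gene, was at -2.88 ± 1.51, with -0.86 without microvesicle array 2 and -4.89 without microvesicle array 1. Actc1 (-0.11 ± 0.46, with a second probe at -1.59) and Myh6 (0.58 ± 0.62) differed by no more than their error. Without microvesicle array 1 they were at 0.34 and 1.34 and without microvesicle array 2 at -0.60 and -0.13. Both were detected in the vesicles on microvesicle array 2 alone. Of 13 tested calcium handling and ion channel genes, 9 lay below and 1 above (median -1.06, adjusted p = 0.741), with 1 lower adjusted over the list alone. The potassium channel gene Kcnh2 was at -3.98 ± 1.55 (-1.93 and -6.08 without microvesicle arrays 2 and 1) and the sodium pump subunit gene Atp1b1 at -1.89 ± 0.89. The gap junction gene Gja1 (2.14 ± 1.73) was detected on microvesicle array 2 and cell array 1, and without microvesicle array 2 it turned to -0.091. Of 7 tested cardiac transcription factor genes, 5 lay below and 2 above (median -0.63, adjusted p = 0.932), with 1 lower adjusted over the list alone. Tbx5 was at least 4.13-fold lower (limma adjusted p = 0.0917), and Myocd, a cofactor of serum response factor, was at 2.18 ± 0.69, with a second probe at -1.17. Nkx2-5 was at -0.34 ± 0.38. Of 13 tested genes of secreted factors, 6 lay below and 0 above (median -0.43, adjusted p = 0.932). The atrial peptide gene Nppa was detected on all 4 RNA arrays at -0.23 ± 0.33, and Tgfb1 was at least 2.76-fold lower. Ryr2 and Gata4 were not detected on any array, and Tnnt2 was not analysed here.

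No list of energy metabolism passed camera's test, and no member passed the threshold. Of 11 tested fatty acid oxidation genes, 9 lay below the cells on both microvesicle arrays and 0 above, with a median of -2.01 (camera adjusted p = 0.250), 3 lower at an unadjusted p under 0.05 and 2 lower adjusted over the list alone. The electron transfer flavoprotein genes Etfb (-3.07 ± 1.49) and Etfa (-3.23 ± 1.25) had the highest cell values, and another Etfa probe was at 0.09. Of 11 tested glycolysis genes, 7 lay below and 1 above (median -1.64, adjusted p = 0.741), with 1 lower adjusted over the list alone. Ldha was at -2.11 ± 1.10 and Gapdh at -2.05 ± 0.92. The 58 tested respiratory chain genes were split, with 19 below and 15 above and a median of -0.52 (adjusted p = 0.118). Cox6b1 (-2.69 ± 1.24) and Cox6a1 (-2.89 ± 1.16), subunits of cytochrome oxidase, were lower by more than their SE. They were picked for their high cell values, and 25 of the 58 genes had a difference above 0. Of 37 tested mitochondrial ribosomal protein genes, 20 lay below and 5 above (median -1.03, adjusted p = 0.741), among them Mrpl38 (-3.15 ± 1.44) and Mrpl10 (-2.16 ± 1.48). Of 8 tested cholesterol synthesis genes, 3 lay below and 1 above (median -0.94, camera adjusted p = 0.887). Fry gave this list an adjusted p of 0.0152 for a shared downward direction. Its members Fdps and Mvd were at -2.21 ± 1.37 and -1.84 ± 1.41, with -0.41 and -0.013 without microvesicle array 2 and -4.02 and -3.80 without microvesicle array 1.

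No list of protein synthesis and turnover outside the ribosome passed camera's test. Of 27 tested translation factor genes, 13 lay below and 4 above (median -1.47, camera adjusted p = 0.808), with Eef1a2 at -1.92 ± 1.15, where another probe was at 0.048, and Eif3d at -3.08 ± 1.57. The 15 tested proteasome genes had 5 below and 2 above (median -0.04, adjusted p = 0.741), and Psmb2 (-3.35 ± 1.55) and Psmb4 (0.01 ± 0.59, -0.64 without microvesicle array 1) lay apart. Of 13 tested chaperone genes, 6 lay below and 1 above (median -0.37, adjusted p = 0.741). Hspb6 was at -2.89 ± 1.21, and Hspa8 was at -3.74 ± 1.19 by its brightest probe and 2.49 by its other probe. The 6 tested genes of the unfolded protein response had 2 below and 0 above (median -0.65, with 0.15 on microvesicle array 1 and -1.51 on microvesicle array 2, adjusted p = 0.808), with 1 lower adjusted over the list alone. Dnajc3 (-0.26 ± 0.78) and Ddit3 (-0.96 ± 1.17) differed by less than their error, and turned to 0.74 and 0.57 without microvesicle array 2. Of 20 tested RNA processing genes, 13 lay below and 4 above (median -1.18, adjusted p = 0.808), with 3 lower adjusted over the list alone. Snrpg was at -1.60 ± 0.89 and Hnrnpc at -1.19 ± 0.77.

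Of 22 tested genes of endosome sorting, tetraspanins and vesicle release, 11 lay below the cells on both microvesicle arrays and 1 above. Their median was -0.96 (camera adjusted p = 0.741), with 2 lower adjusted over the list alone. Mfge8, whose protein is known from vesicle surfaces, was at -4.09 ± 1.58, and the membrane raft gene Flot2 at -1.68 ± 1.0. Of 18 tested actin and tubulin cytoskeleton genes, 12 lay below and 1 above (median -0.80, adjusted p = 0.741), with 1 lower adjusted over the list alone. Actb was at -3.91 ± 1.13 and Tubb5 at -0.58 ± 0.51. Of 17 tested cell cycle genes, 11 lay below and 1 above (median -1.24, adjusted p = 0.741), with Aurka at -1.97 ± 1.07 and Birc5 at -0.92 ± 1.0 (0.34 without microvesicle array 2). The 12 tested histone genes had 5 below and 2 above (median -0.68, with 0.12 and -1.26 on microvesicle arrays 1 and 2, adjusted p = 0.741), among them H2bc7 (-2.24 ± 1.38) and H2bc11 (-1.82 ± 1.06). The 48 tested zinc finger genes had 16 below and 11 above (median -0.34, with 0.22 and -1.05 on microvesicle arrays 1 and 2, adjusted p = 0.741). Among them were Zbtb17 (-1.56 ± 1.47, turning to 0.37 without microvesicle array 2) and Zbtb8b (-1.27 ± 0.87). For the sarcomere, translation factor, respiratory chain, mitochondrial ribosome, proteasome, cholesterol, chaperone, histone and zinc finger lists, camera gave the direction as up although the median and mean were below 0, since it sets the test statistics of a list against those of the other tested genes and not against 0.

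**Figure D3:**
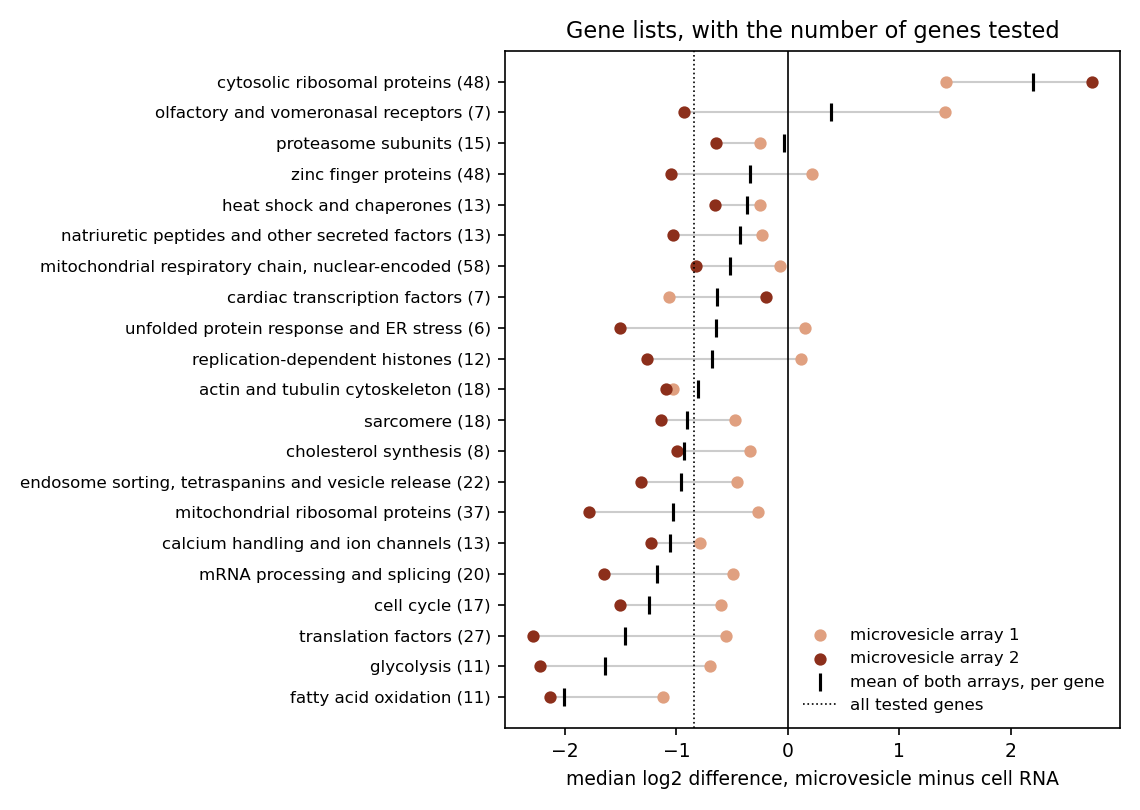
Median log2 difference between microvesicle and cell RNA (horizontal axis) for the 21 tested gene lists, with the number of genes tested in brackets. Pale and dark points are the medians for microvesicle arrays 1 and 2, bars are the medians of the mean difference per gene and the dotted line is the median of all tested genes (-0.84). Cytosolic ribosomal proteins (2.20) stand apart.

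Markers of other cell types were mostly not detected. Of 18 leukocyte genes on the array, 0 were detected on both arrays of either group. Of 47 keratin genes, 0 were on both arrays of either group and 2 were on microvesicle array 2. Hepatocyte and serum protein genes had 0 of 17 on both cell arrays and 1 on microvesicle array 2, and erythrocyte genes had 1 of 9 on both cell arrays and 0 on both microvesicle arrays. Fibroblast genes had 2 of 20 on both cell arrays and 1 on both microvesicle arrays, with 1 lower adjusted over the list alone. The endothelial list had 3 of 17 and 1, the neuronal list 2 of 18 and 1, and the adipocyte list 1 of 11 and 1. Of 25 immediate early genes, 4 were on both cell arrays and 3 on both microvesicle arrays. Of 3 nuclear noncoding RNA genes, 1 was detected on microvesicle array 2 and 0 on both cell arrays. Of 1214 olfactory and vomeronasal receptor genes, 5 were on both cell arrays and 0 on both microvesicle arrays. The 7 that were tested, with Olfr724 at 0.54 ± 1.19 and Olfr748 at -0.33 ± 0.63, had a median of 0.39 (camera adjusted p = 0.486), with 1.42 and -0.93 on microvesicle arrays 1 and 2. It turned to -0.16 with median scaling. Olfr724 turned to -1.10 without microvesicle array 1 and Olfr748 to 0.39 without microvesicle array 2. Without microvesicle array 2 and with chip as a block, camera called this list higher as well, and without microvesicle array 1 it called the respiratory chain list.

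The third comparison asked which probe sequences the microvesicle DNA contained. The signal was carried by few probes, led by the ribosomal protein gene Rpl23 at a raw signal of 7242 ± 259 (SE over 38 beads), 103 times the median of the array. An unnamed probe followed at 448, then the steroid dehydrogenase gene Hsd3b2 (367 ± 19.3), the death receptor gene Tnfrsf10b (356 ± 11.2), a second unnamed probe (254), Erich5 (204 ± 8.60), the perforin gene Prf1 (176 ± 6.91) and the CTCF paralogue gene Ctcfl (175 ± 6.01). Rhbdl2, Irgm1 and Mid1 followed at about 154 each, and the small nuclear RNA gene Rnu6 was at 135 ± 4.88. In all, 11 probes were over 2 times the median of the array and 37 were over 1.5 times. The 343 detected probes (315 genes) had a median signal of 96.8, close to the lowest detected signal of 93.5, and chance gives 257. At a detection p under 0.05 there were 1299, where chance gives 1285, and 49 probes lay above every negative control. With 1 array, none of these values has a replicate check.

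Most of the brightest DNA probes listed above were also bright on microvesicle RNA array 2. Rpl23 gave raw signals of 5691 and 28246 on microvesicle RNA arrays 1 and 2, against 3075 and 1562 on the cell arrays. Irgm1, an interferon-induced GTPase gene, gave 648 and 11259 against 376 and 210, and Rnu6 gave 649 and 3790 against 134 and 73.7. Erich5, Prf1 and Rhbdl2 gave 163, 187 and 134 on microvesicle RNA array 1 and 4430, 4222 and 3115 on microvesicle RNA array 2. The unnamed probes gave 19551 and 5950 on microvesicle RNA array 2. Hsd3b2 was detected on that RNA array only, at 3353. Others were dim on the RNA arrays. Tnfrsf10b and Mid1 were detected on microvesicle RNA array 2 only, at 271 and 136, and Ctcfl was not detected on any RNA array. On the normalized scale, which quantile normalization stretches for the DNA array, the genes furthest above the highest RNA array were Ctcfl, Mid1, Rchy1, Nr0b1, Ahsg, Calcoco1, Gemin2, Eddm3b, Ttc41 and Fam122b. In raw signal, all but Ctcfl and Mid1 were at 105 to 115. In raw signal, Nr0b1, Ahsg, Calcoco1 and Ttc41 were no brighter on the DNA array than on microvesicle RNA array 2. Fam122b was dimmer (110 against 155). Background differed, with a median signal of 70.2 on the DNA array and 90.9 on microvesicle RNA array 2. Ttc41, at 105 on both arrays, was detected on the DNA array and not on microvesicle RNA array 2.

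**Figure D4:**
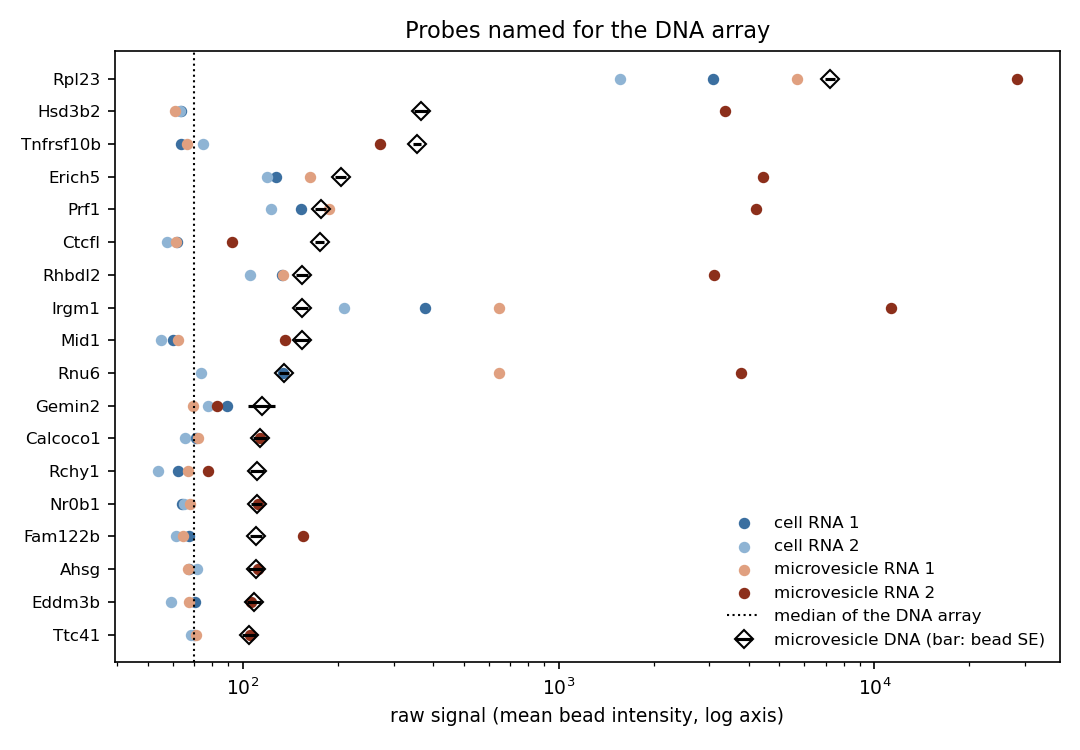
Raw signal (mean bead intensity, log axis) of the genes named for the DNA array. Diamonds are the DNA array with the bead SE, coloured points are the RNA arrays and the dotted line is the median of the DNA array (70.2). Rpl23 (7242) stands far above the other genes, most of which lie near background.

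Of the 343 probes detected on the DNA array, 57 (16.6%, 12.8 to 20.99) were on both microvesicle RNA arrays, where independent lists would share 21.3. On both cell arrays there were 73, where independent lists would share 46.3. On microvesicle RNA array 2 there were 206 (60.1%, 54.7 to 65.3), where independent lists would share 74.8, and 112 of them were on no other RNA array. On no RNA array at all were 123 (35.9%, 30.8 to 41.2). Across all probes the normalized log2 values of the DNA array correlated at 0.14 with the mean of the microvesicle RNA arrays.

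The gene lists had few members on the DNA array. Of 63 cytosolic ribosomal protein genes 2 were detected, where 1.15 would be expected from the detected share of genes, and of 327 zinc finger genes 6 were detected, where 5.97 would be expected. Of 1214 receptor genes 14 were detected, where 22.2 would be expected. These expected numbers count genes and do not allow for the number of probes per gene. By probe, 1.06% of the 1326 receptor probes were detected, against 1.33% of all probes. List medians against the microvesicle RNA are not given, since most list genes lay at background on the DNA array.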

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

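The crossed pairing and the list tests with a chip or replicate block were chosen after seeing the data. Causes of the changes below were not tested unless the setting shows them by its construction.

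The RNA comparison called 0 probes higher and 0 lower. It did so too with no background correction, with normexp, with the DNA array in the normalization, with the deposited processed values, with a filter at detection p 0.05 or on all 4 arrays, and with a 2-fold limit. Median scaling gave 7 higher and 1651 lower, no normalization 5 and 1416, no filter 16 and 163, a variance trend 10 and 677, and chip as a block 968 and 1735. Leaving out each array gave 0 to 997 higher and 0 to 2718 lower, with calls only where a microvesicle array was left out, so that the spread came from the cells. The replicate block gave 0 and 0. Same-numbered arrays deviated in opposite directions (correlation -0.24), and the crossed pairing, which this hints at, also gave 0 and 0. Chip as a random block could not be fitted with 4 arrays and was not run. The median difference of all tested probes was -0.87, with -0.35 under the filter at detection p 0.05 and 0.016 with no filter. That of all tested genes moved from -0.84 to -1.28 with median scaling and to -0.44 with no background correction.

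At a detection p under 0.05, both microvesicle arrays shared 2402 probes, 89.3% of them on both cell arrays. Above every control the share was 97.48% of 1153. Leaving out each array gave 1595 to 5605 probes and shares of 37.0% to 98.2%, where a left-out microvesicle array means that the count is that of the other. The DNA array had 1299 probes at a detection p under 0.05, 24.6% of them on both microvesicle RNA arrays, and 49 above every control, 28.6% of them on both. Its correlation with the microvesicle RNA arrays moved from 0.14 to 0.19 with no normalization and with the deposited processed values, and lay between 0.12 and 0.13 against either array alone.

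Camera called 1 list, and so it did with the mean of a gene's probes, no normalization, median scaling and the replicate block. It called 0 lists with an estimated correlation, where the ribosomal median of 2.20 kept an adjusted p of 0.600, and fry gave that median of 2.20 an adjusted p of 0.0868. With chip as a block it called 2 lists, and leaving out each array gave 1 to 2. The ribosomal median stayed between 1.31 and 2.69 over these settings. Of the 21 tested lists, 20 kept the sign of their median under every scaling, and the receptor list did not. The medians on microvesicle arrays 1 and 2 differed in sign in 4 lists, those of histones, zinc fingers, the unfolded protein response and receptors.

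Of 69 tested genes named for RNA, 56 kept the sign of their difference under every setting that could measure them. Rplp1 and Rps2 went to 0 with chip as a block and without microvesicle array 2. This was fixed by quantile normalization, which gave each of them the same value on microvesicle array 1 and both cell arrays. The size of the differences was less stable, as 37 of the 69 genes moved by more than 2 on the log2 scale between the settings that leave out an array. Tnnc1 went from -4.89 to -0.86, Kcnh2 from -6.08 to -1.93, Eif3d from -5.08 to -1.09 and Cox6b1 from -4.18 to -1.03, each lowest without microvesicle array 1. The sign changed in 11 genes, none of them past the threshold. With median scaling and with no normalization, Myl4 turned to -0.53 and -0.46, Psmb4 to -1.12 and -1.04, and Olfr724 to -0.16 and -0.086, and Psmb4 was at -0.028 with the deposited processed values. With chip as a block, Birc5 was at 0.35, Dnajc3 at 0.69, Ddit3 at 0.54, Zbtb17 at 0.36, Olfr748 at 0.40, Gja1 at -0.13 and Myh6 at -0.13. Leaving out each array gave ranges of -0.64 to 0.64 for Psmb4, -2.20 to 0.34 for Birc5, -1.23 to 0.74 for Dnajc3, -2.62 to 0.57 for Ddit3 and -3.58 to 0.37 for Zbtb17. The ranges were -1.10 to 2.18 for Olfr724, -1.21 to 0.39 for Olfr748, -0.091 to 4.61 for Gja1, -0.60 to 0.34 for Actc1 and -0.13 to 1.34 for Myh6.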

Other observations

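The tests of a larger amount of the same RNA and of a signal shared by chip 2, in the account of microvesicle RNA array 2, were chosen after the result was seen.

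The small nuclear RNA gene Rnu6, whose U6 RNA works in the spliceosome, was among the probes that stood furthest above the cells, at a log2 difference of 5.61 (limma adjusted p = 0.0917), and it was picked out after its value was seen. Its raw signal was 649 and 3790 on the microvesicle RNA arrays against 134 and 73.7 on the cell arrays. The same probe was detected on the microvesicle DNA array, at 135, and a contribution of DNA to its RNA signal was not tested. Different probes of a gene often disagreed. Among 439 genes with several tested probes, 118 had differences of opposite sign, as with the chaperone gene Hspa8 at -3.74 and 2.49.

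Microvesicle RNA array 2 stood apart from the other RNA arrays, with 3166 probes detected on it alone. A signal common to chip 2 is argued against as the whole of it, since the DNA array on that chip showed a median of 2.34% (1.81 to 2.88) of the excess of these probes. A part stays open, as 3.54% of them were detected on the DNA array against 1.33% of all probes. A larger amount of the same RNA is argued against as the whole of it, since it would not dim the bright probes of array 1. Of 854 bright probes that array 1 shared with the cells, 25.2% (22.3 to 28.2) had under 0.5 times their excess over the array median on array 2, and 3.86% were not detected there. Genomic DNA or unspecific amplification would light receptor probes as often as others, and the ratio of the shares was 0.0431 (0.0225 to 0.0827) among probes on neither cell array. RNA of another cell type had no support among the 8 lists tested, of which 0 exceeded the 21.8% of all probes, and other types stay open. Other parts of transcripts that the cells carry stay open. Of the 3166 probes, 1594 belonged to genes with several probes, and 29.0% (26.8 to 31.3) of these had another probe on both cell arrays. The share was 14.0% among probes on no RNA array. It sets no upper limit, since cells may carry a gene whose other probe was not detected. No biological explanation was tested for a difference between replicates.

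The DNA array shared 206 of its 343 probes with microvesicle RNA array 2. Vesicle RNA carried into the DNA sample would show the brightest RNA probes, and 10 (4.9 to 17.6) of the 100 brightest probes of that array were detected, against 1.33% of all probes, so it may account for single probes but not for the set. Probe-specific background stays open. The 112 probes on the DNA array and microvesicle RNA array 2 alone were ranked among undetected probes of microvesicle RNA array 1, on chip 1. Their median percentile was 88.2 (81.0 to 91.8). They were chosen for detection on microvesicle RNA array 2, and raw signals of the microvesicle RNA arrays correlated in rank at 0.45 over all probes. A high percentile can follow from that alone, and probes on microvesicle RNA array 2 but not on the DNA array were not set beside them. A signal common to chip 2 cannot be told apart, since 1 probe decided its ratio of 1.36 (0.189 to 9.73). Over receptor probes, the ranks of the DNA array correlated at 0.68 with microvesicle RNA array 2 on the same chip, and at 0.40 with microvesicle RNA array 1 and 0.29 with cell array 1 on the other, which goes with a shared chip. That the vesicles carry both DNA and RNA of these genes stays open and untested.

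Cytosolic ribosomal protein transcripts had a median log2 difference of 2.20 and stood above the other tested genes by camera, a call lost with an estimated correlation (adjusted p = 0.600). Abundance in the cells is argued against, as the list's median of 2.20 lay at percentile 100 of lists matched on the cell level (95% of them from -1.53 to -0.68). Short genes are argued against in the same way, at percentile 100 of lists matched on genomic length, and over the other genes length and difference correlated in rank at 0.06. Genomic copies brought in by DNA cannot be told apart. The list's signal on the DNA array lay at percentile 56.8, but only 2 of its 63 genes were detected there, so its median reflects background, and 1 of the 2, Rpl23, was the brightest probe of that array (7242). A preferential release of these messages in vesicles stays open, and so do effects of transcript length and RNA integrity, which were not tested.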
